A study of Sus scrofa with 12 samples.

How the data were processed

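RNA was sequenced from 12 libraries of pig cells, 3 in each of 4 groups. The groups were fetal fibroblasts, parthenogenetic embryonic stem cell (ESC) line 3, parthenogenetic ESC line 7, and ESC line 11 from an embryo made by in vitro fertilisation (IVF). Per the labels, the ESCs were sorted for SSEA1 on magnetic columns before RNA extraction, to remove differentiated and feeder cells, and polyA RNA was read as 100 bp paired ends from TruSeq libraries.

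The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), computed by the authors, in 1 table of 30012 loci by 12 libraries. The submitters' processing notes name STAR 2.4.0b, Cufflinks 2.1.1 and the genome build Sscrofa10.2, without saying which step each one did. The table holds 20688 loci with an Ensembl identifier and 9092 loci marked as absent from the annotation. It gives no read counts and no depth, so the depth behind each value is unknown and no counting interval can be given. Values were not whole numbers, and libraries differed in their summed FPKM. Strandedness, the handling of multiply mapped reads and bias correction were not stated. All 12 columns matched a labelled sample, and none was left out.

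Values were used as log2(FPKM + 1) without further scaling. Loci were tested if they had an FPKM of at least 1 in at least 3 libraries, which left 18278 loci, 13185 of them Ensembl loci and 5093 unannotated. Group means of all 12 libraries were fitted in 1 model with limma 3.58.1 in R 4.3.3, with moderated variances that followed the mean expression. A locus was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1, and all tests were two-sided. The mean of the 3 ESC lines was compared with fibroblasts, the mean of the 2 parthenogenetic lines with the IVF line, and line 7 with line 3. Each line was also compared with fibroblasts, and each parthenogenetic line with the IVF line. Errors beside FPKM values are standard deviations between libraries, and errors beside log2 differences are standard errors from limma. Independent overlap counts were the products of the single shares. Overlaps were also counted in 20 simulated data sets with no changed gene. Nothing in the labels says that the 3 libraries of a group came from separate cultures. The p-values therefore measure only the spread between libraries, which may be technical.

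The gene lists (27 lists with 459 genes), the comparisons, the thresholds, the rule for named genes and most of the alternatives were chosen before the data were examined. Of the listed genes, 409 were in the table and 331 were tested, and 25 lists had at least 3 tested members. A symbol on several loci was represented by the locus with the highest mean FPKM. Lists were tested against all other loci with camera in limma, with a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. List p-values were adjusted over the 25 lists of a comparison. The rule named up to 6 genes with the largest difference in each direction, with a mean FPKM of at least 5 in the higher group and no overlap between the sides. It also named up to 4 called members of each list and a fixed set of marker and imprinted genes. Some list members outside the rule are also named, chosen after their values were seen. Some genes that fit the rule are not reported here. The largest differences often fell on short unannotated loci. The same ranking was therefore also made over Ensembl loci alone, a choice made after the values were seen.

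The alternatives were other pseudocounts, filters and thresholds, quantile normalization, scaling to the same sum or by median ratios, other variance settings, library weights, a replicate term, summing loci of a symbol, and leaving out each library in turn. Ensembl loci alone, and loci of at least 1 kb alone, were added after the data were seen. The model was tested on simulated data with the spread of these libraries. Moved loci were taken from those above a minimum mean expression. Of 67 loci moved by a log2 difference of 1.5 in the ESC and fibroblast comparison the model recovered 92.5%. It made 0 false calls there and between parthenogenetic and IVF ESCs, and 1 false call between ESC7 and ESC3. With camera, a moved list reached an adjusted p of 3.73e-103, and 0 of 24 unmoved lists passed. The simulated noise was independent between loci, so false passes of lists with correlated members were not tested. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.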

Results

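Gene expression was measured in 12 RNA-seq libraries. Fibroblasts came from a fetus at day 30 and were at passage 6. The 2 parthenogenetic lines, here ESC3 and ESC7, derive from activated eggs without a sperm genome. The line ESC11 derives from an IVF embryo. Each group had 3 libraries. Between 21898 and 24100 loci had an FPKM above 0 in a library, and the median FPKM of those loci was 4.59 to 5.05. Loci spanning under 300 bp, nearly all absent from the Ensembl annotation, held 54.8% to 80.6% of a library's summed FPKM, so values on such loci are named as short loci below. Coordinates are those of the deposited table, on Sscrofa10.2.

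Libraries clustered by group. The first principal component held 78.0% of the variance and parted the fibroblasts from all 9 ESC libraries. The second held 7.22% and placed ESC3 and ESC7 at opposite ends, with IVF ESC11 between them. Across loci, the median correlation between libraries was 0.981 to 0.985 within a group, 0.953 to 0.960 between ESC lines, and 0.723 to 0.728 between ESCs and fibroblasts. These are correlations across genes, which are not independent replicates.

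**Figure D1:**
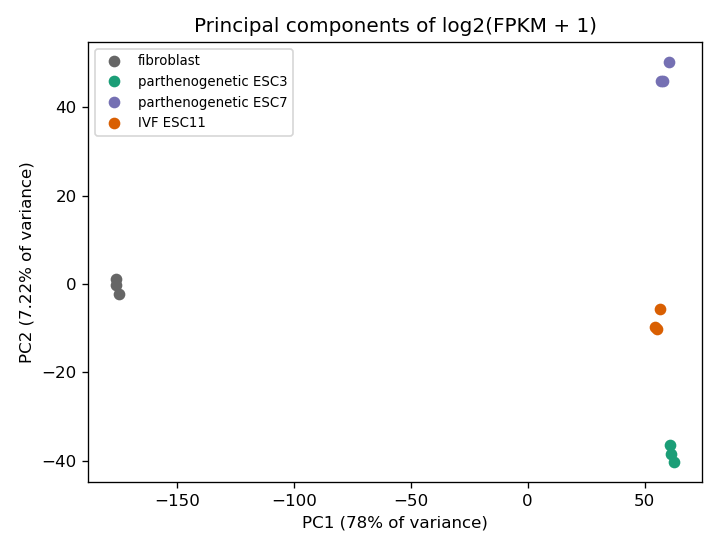
Each point is 1 library, placed by the first (78.0% of variance) and second (7.22%) principal components of log2(FPKM + 1) over the tested loci, coloured by group (n = 3 each). Fibroblasts lie apart on the first axis, and the 3 ESC lines part on the second.

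The comparison of ESCs with fibroblasts asks which genes set the stem cell lines apart from a differentiated cell of the same species. POU5F1, the core pluripotency transcription factor (chromosome 7, 27262624 to 27268634), had an FPKM of 757 ± 26.0 in ESCs (SD, n = 9) and 0.0248 ± 0.0429 in fibroblasts (SD, n = 3), a log2 difference of 9.53 ± 0.04 (adjusted p = 7.22e-17). LIN28A, an RNA-binding protein of early embryonic cells, rose to 694 ± 34.6 (SD, n = 9), SOX2 to 211 ± 11.8 and NANOG to 96.6 ± 12.5, while fibroblast means of these genes were under 1. COL3A1, a collagen of connective tissue (chromosome 15, 104067018 to 104105776), fell by 10.25 ± 0.13 on the log2 scale, from 1366 ± 43.2 (SD, n = 3) to 0.136 ± 0.206 (SD, n = 9). COL1A1, the main fibrillar collagen chain, fell from 5307 ± 169 to 14.8 ± 4.84, and VIM, the mesenchymal intermediate filament, from 6712 ± 186 to 58.5 ± 9.20.

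Pluripotency genes are given by class, and the classes were not tested against each other. Of 16 core pluripotency genes, 15 rose and 0 fell, with a median log2 difference of 5.19 (adjusted p = 3.26e-05), and among them DNMT3B, a de novo DNA methyltransferase, reached 893 ± 71.9. L1TD1, read on an unannotated locus, was the member not called, at a log2 difference of -0.78 (-1.15 and called after quantile normalization). Of 14 genes of the primed epiblast, the later pluripotent state, 11 rose and 1 fell (median 2.27, adjusted p = 0.00129; adjusted p = 0.21 with an estimated correlation). OTX2 was listed at 0 in fibroblasts and reached 57.3 ± 15.0 in ESCs, ZIC2 rose from 0.254 to 39.8, and SFRP2, a secreted WNT antagonist, fell from 91.7 to 38.1. FGF5, a primed marker, stayed below the filter, with no library above 0.364. Of 12 genes of the naive state, 6 rose and 4 fell (adjusted p = 0.862). ZFP42 rose to 113 ± 11.9 and KLF5 to 41.1 ± 8.33, while KLF4 fell from 23.9 ± 0.846 to 8.61 ± 1.16 and TBX3 was listed at 0 in every ESC library. DPPA3, on an unannotated locus, reached 2.13 ± 0.673, and KLF17, TFCP2L1, ESRRB and NR0B1 were below the filter.

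The cells also differed in epithelial and mesenchymal genes. All 17 epithelial genes rose (median 5.76, adjusted p = 5.85e-07), including KRT18, a simple-epithelium keratin, at 433 ± 78.0, CLDN4, a tight-junction claudin, at 420 ± 56.1, and EPCAM, listed at 0 in fibroblasts, at 224 ± 14.0. CDH1, the epithelial cadherin, was read on an unannotated scaffold locus at 683 ± 141 in ESCs and 0 in fibroblasts. Of 27 fibroblast and matrix genes, 26 fell and 1 rose (median -5.34, adjusted p = 6.85e-15). THY1, a fibroblast surface marker, fell from 207 ± 5.70 to 7.26 ± 0.842, and FBLN1, a matrix glycoprotein, rose from 0.714 ± 0.144 to 39.5 ± 2.97. All 13 mesenchymal transition genes fell (median -4.06, adjusted p = 2.76e-08), among them ZEB1 by 5.80 and TWIST1 by 5.57 on the log2 scale. All 10 smooth muscle and contractile genes fell (median -4.49, adjusted p = 2.76e-08), with ACTA2, smooth muscle actin, at 1876 ± 102 in fibroblasts and 1.96 ± 0.745 in ESCs. All 16 HOX cluster genes, which pattern the body axis, fell (median -2.55, adjusted p = 3.7e-09), and HOXC8 fell from 339 ± 18.2 to 5.86 ± 3.96.

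**Figure D2:**
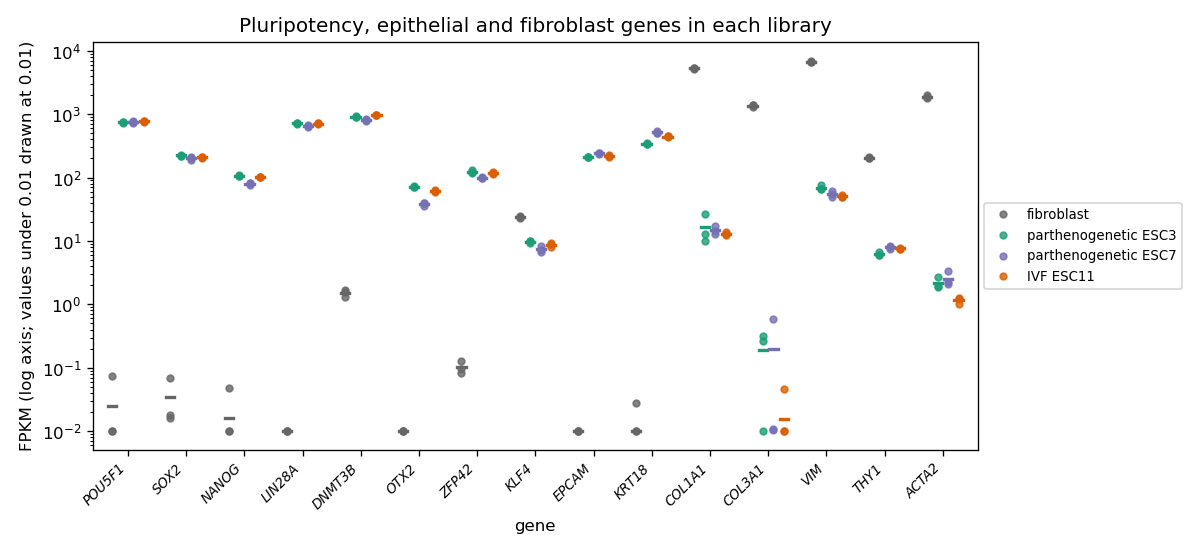
FPKM on a log axis of pluripotency, epithelial and fibroblast genes, where each point is 1 library, each line the mean of 3 libraries, and values under 0.01 are drawn at 0.01. POU5F1 averages 757 in ESCs and 0.0248 in fibroblasts, and COL1A1 averages 14.8 and 5307.

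Metabolic and cycle genes moved less, and their counts depended on scaling. Of 26 oxidative phosphorylation genes, 18 rose and 0 fell (median 1.17, adjusted p = 3.26e-05; adjusted p = 0.225 with an estimated correlation), such as UQCRFS1, a complex III subunit, from 24.3 ± 0.622 to 146 ± 8.68. Of 21 cell cycle genes, 13 rose and 0 fell (median 1.04, adjusted p = 0.0173; adjusted p = 0.335 with an estimated correlation), such as CCNE1, the G1/S cyclin, from 5.69 ± 0.319 to 31.5 ± 2.07. The median over all loci was 0.44, and 0.12 after quantile or median-ratio scaling. Relative to it, the oxidative phosphorylation median was 0.731 as deposited and 0.70 after median-ratio scaling, which left 7 members called, and the cell cycle median was 0.599 and 0.559, which left 3 called. Of 17 glycolysis genes, 5 rose and 1 fell (adjusted p = 0.445). SLC2A3, a glucose transporter, rose from 5.20 ± 0.183 to 266 ± 19.8, LDHB rose by 1.89, and LDHA, the other lactate dehydrogenase subunit, fell by 1.95 on the log2 scale. Of 13 senescence and cycle inhibitor genes, 10 fell and 3 rose (median -3.48, adjusted p = 0.000237). CDKN2A was at 42.1 ± 3.90 in fibroblasts and listed at 0 in ESCs. IGFBP3, a carrier of insulin-like growth factors, IL6 and CDKN2D were the 3 that rose.

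Signalling targets split in both directions. The ESC medium held FGF2 at 20 ng/mL, activin A (ActA) at 5 ng/mL, CH at 1.5 µM and the tankyrase inhibitor IWR-1 at 2.5 µM. Of 13 FGF and MEK feedback targets, 6 rose and 3 fell (adjusted p = 0.862). The phosphatase DUSP6 rose from 7.52 ± 0.718 to 78.1 ± 13.0 and DUSP4 by 3.38 on the log2 scale, while IER3, an immediate early gene, fell by 3.60. Of 10 NODAL and activin targets, 4 rose and 4 fell (adjusted p = 0.597), with FOXH1, a SMAD partner, rising from 0.105 ± 0.0832 to 177 ± 9.83 and LEFTY2, a NODAL antagonist, from 0.202 ± 0.0359 to 55.2 ± 37.3. Of 9 WNT feedback targets, 3 rose and 4 fell (adjusted p = 0.373). LEF1, a WNT-responsive transcription factor, fell from 8.90 ± 0.733 to 0.0747 ± 0.0594 and APCDD1, a WNT inhibitor, rose by 3.10 on the log2 scale. The FGF and MEK median was 0.31 and turned to -0.04 after median-ratio scaling, the NODAL median was 0.07 and turned to -0.13, and the WNT median was -0.01 and turned to 0.04 with scaling to the same sum. Relative to the median of all loci, each of these lists was below 0 with every scaling.

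The remaining lists moved partly. Of 19 DNA methylation and chromatin genes, 6 rose and 0 fell (adjusted p = 0.0907), with TET1 at 26.2 ± 1.75 and JARID2 at 85.4 ± 12.3 in ESCs; after median-ratio scaling 5 rose and 1 fell. Of 13 listed germ cell genes 3 were tested, DND1, KIT and PRDM1, and all of these rose (adjusted p = 0.0634). PRDM1 was at 0.99, below the fold minimum, after quantile normalization. The untested members, such as DDX4 and DAZL, were below the filter in these libraries, with a highest FPKM of 1.85, for SYCP3. Of 5 neural genes, 3 fell and 0 rose (adjusted p = 0.0429; adjusted p = 0.166 with an estimated correlation), namely PAX6, NES and NCAM1. Of 9 trophectoderm genes, 3 rose and 5 fell (median -1.59, but 1.07 after scaling to the same sum, where 5 were tested; adjusted p = 0.139), with TFAP2C rising by 3.79 and DAB2 falling from 80.6 ± 5.64 to 0.541 ± 0.150. Of 3 mesendoderm genes WNT3 rose and MESP2 fell (median 0.27, but -0.15 after quantile normalization; adjusted p = 0.735), and WNT3 was at 0.88 after that normalization. Of 4 blood and endothelial genes 1 rose and 2 fell (adjusted p = 0.43). Of 14 immediate early and heat shock genes, 5 rose and 2 fell (adjusted p = 0.906), with FOS rising from 4.28 ± 0.618 to 119 ± 26.0. Of 13 genes for SSEA1 synthesis and surface markers, 4 rose and 4 fell (adjusted p = 0.206), with PODXL, a sialomucin of stem cells, rising by 7.00 and CD44 falling by 4.87 on the log2 scale. Skeletal muscle genes and X- and Y-linked marker genes had fewer than 3 tested members each.

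Of 15 paternally expressed imprinted genes, 2 rose and 7 fell in ESCs against fibroblasts (median -0.84, adjusted p = 0.0226; adjusted p = 0.171 with an estimated correlation). The ESC mean joins lines that differ in this list, as given below for the parthenogenetic lines. Of 14 maternally expressed imprinted genes, 4 rose and 4 fell (median 0.29, but -0.03 after median-ratio scaling; adjusted p = 0.735).

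In all, 7874 of 18278 loci were called between ESCs and fibroblasts, 5144 higher and 2730 lower in ESCs. After quantile normalization the split was 3748 higher and 3614 lower, so the excess of higher loci depends on scaling. With a pseudocount of 5, the low-level genes TBX3, DPPA3, MESP2, WNT3, PRDM1 and IL6 were at -0.51, 0.51, -0.84, 0.37, 0.36 and 0.43, below the fold minimum. Against fibroblasts, 8062 loci were called in ESC3 (5230 higher, 2832 lower), 7941 in ESC7 (5330 higher, 2611 lower) and 7847 in ESC11 (5007 higher, 2840 lower). These splits also depended on scaling, with 3867 higher and 3661 lower in ESC3 after quantile normalization. Scaling to the same sum gave 1480 and 2260 in ESC3, 2120 and 1753 in ESC7, and 6593 and 1114 in ESC11. All 3 lines shared 4079 higher and 2346 lower loci, 6425 in total, where independent calls would give 418 and 62.9 and simulated unchanged data gave 0. The lines share the same fibroblast libraries, too few to divide, so part of that excess may come from them. The simulated data hold no changed gene, so their 0 cannot show how large that part is. Of the 25 lists, 12 passed camera's test, 5 up and 7 down, and 7 passed with an estimated correlation. Counts adjusted over the list alone were the same as those over all loci for each of the 25 lists. The naive, mesendoderm, FGF and MEK, NODAL, maternally expressed and SSEA1 lists had a median, mean and test that differed in sign.

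The comparison of parthenogenetic with IVF ESCs asks which genes depend on a paternal genome, although 2 lines against 1 cannot part origin from line. SNRPN, an imprinted splicing-factor gene read from the paternal allele (scaffold GL896379.1, 22821 to 48725), had an FPKM of 0.134 ± 0.107 in parthenogenetic ESCs (SD, n = 6) and 154 ± 4.95 in IVF ESCs (SD, n = 3), a log2 difference of -7.10 ± 0.07 (adjusted p = 5.02e-12). PEG10, a paternally expressed gene derived from a retrotransposon and read on an unannotated locus (chromosome 9, 81651789 to 81655368), fell from 81.5 ± 3.06 to 0.279 ± 0.355. In contrast PAGE4, an X-linked gene of the cancer/testis class (chromosome X, 48522892 to 48530860), rose from 2.37 ± 0.820 in IVF to 1032 ± 367 in parthenogenetic ESCs, and was listed at 0 in fibroblasts. POU5F1 was at 748 ± 26.0 in parthenogenetic and 775 ± 16.1 in IVF ESCs, and 0 of 16 core pluripotency genes were called (adjusted p = 0.303), with NANOG at -0.13 (adjusted p = 0.0154), below the fold minimum.

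Of 15 paternally expressed imprinted genes, 9 fell and 0 rose in the mean of the parthenogenetic lines (median -1.28, adjusted p = 2.49e-15; adjusted p = 0.00349 with an estimated correlation). NAP1L5 fell from 6.01 ± 0.0733 to 0.0278 ± 0.0349, PLAGL1, a zinc-finger regulator of growth, from 7.73 ± 0.562 to 0.436 ± 0.0977, and NNAT, neuronatin, from 11.1 ± 0.325 to 1.68 ± 0.221. Of the 9, 6 were called in each line against IVF ESC11, and the others in 1 line. DIRAS3, a RAS-related growth inhibitor, fell by 1.05 on the log2 scale (1.12 in ESC3, 0.98 in ESC7) and PEG3, a zinc-finger gene, by 1.28 (0.58 in ESC3, 1.99 in ESC7). MAGEL2 did not fall in both lines: its mean difference of -1.41 joins 0.596 in ESC7 with 21.4 in ESC3, which lies above the 14.9 of IVF ESC11. SGCE fell on a short unannotated locus of 205 bp by 6.81 ± 1.25. Those not called were MEST at -0.98, which passes the fold minimum at -1.02 without the IVF library 3, MKRN3 at -0.58, or -1.82 and called with a pseudocount of 0.1, INPP5F, IMPACT, L3MBTL1 and BLCAP. IGF2 was listed at 0 in every library, and H19, CDKN1C and XIST are not analysed here. Fibroblasts, with both parental genomes, had SNRPN at 27.4 ± 0.483, PEG10 at 1442 ± 84.3 and NNAT at 8.65 ± 0.543.

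**Figure D3:**
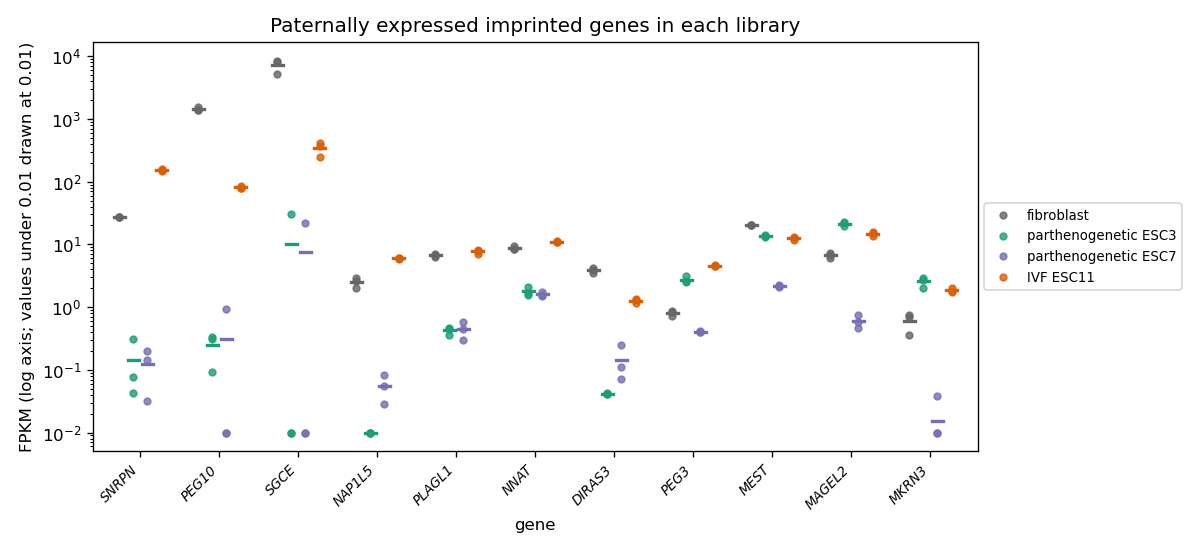
FPKM on a log axis of paternally expressed imprinted genes, where each point is 1 library, each line the mean of 3 libraries, and values under 0.01 are drawn at 0.01. SNRPN averages 0.134 in parthenogenetic and 154 in IVF libraries, while MAGEL2, MEST, PEG3 and MKRN3 lie higher in ESC3 than in ESC7.

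Of 14 maternally expressed imprinted genes, 1 rose and 1 fell (median 0.00, but -0.03 after median-ratio scaling; adjusted p = 0.605), both on short unannotated loci, ATP10A on 186 bp and KCNQ1 on 124 bp. KCNQ1 fell in the mean alone, as the lines went opposite ways, with 0 in ESC3 and 10174 in ESC7 beside 2112 in IVF ESC11. The ATP10A difference was 1.94 there and -0.01 on its Ensembl locus. UBE3A was at 43.6 ± 1.98 in parthenogenetic and 44.9 ± 0.35 in IVF ESCs, IGF2R at 122 ± 20.2 and 110 ± 11, and GRB10 at 15.8 ± 1.07 and 14.6 ± 0.92. A doubling of FPKM stays below the fold minimum on log2(FPKM + 1), so the counts of called genes could not show one.

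Genes outside the imprinted lists also differed. VTI1A, a vesicle-fusion protein, rose from 5.48 ± 1.51 to 163 ± 87.5, CYP2C18, a cytochrome P450, from 0.242 ± 0.0916 to 7.06 ± 2.99, TNFRSF10B, a death receptor, by 2.27, and SLC1A3, a glutamate transporter, by 1.50 on the log2 scale. MUCAP_PIG was listed at 0 in IVF ESCs and had 12.9 ± 13.1 in the parthenogenetic lines. KBTBD6, a ubiquitin-ligase adaptor, was at 12.4 ± 0.739 in IVF ESCs, at 4.57 ± 0.758 in fibroblasts, and listed at 0 in all 6 parthenogenetic libraries. FJX1, a secreted kinase-family protein, fell from 14.1 ± 0.961 to 1.95 ± 0.105. FUT4, a fucosyltransferase that makes the SSEA1 epitope used for sorting, fell from 2.97 ± 0.127 to 0.272 ± 0.146. FUT9, which also makes it, was at 3.68 ± 0.790 in parthenogenetic and 4.23 ± 0.635 in IVF ESCs. Of 13 SSEA1 and surface genes, FUT4 was the one that fell and ITGA6, on an unannotated locus of 172 bp, the one that rose (adjusted p = 0.384); ITGA6 was at 1.00, below the fold minimum, without IVF library 3. TWIST2 was the one of 13 mesenchymal genes called, higher by 1.20 (adjusted p = 0.268 for the list). HOXC8 was the one of 16 HOX genes called, higher by 1.42 (adjusted p = 0.0522 for the list), and its adjusted p was 0.0633 without IVF library 2 and 0.0524 without IVF library 3.

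The cell cycle list passed downward with 0 of 21 members called (median -0.09, adjusted p = 0.0254; adjusted p = 0.541 with an estimated correlation), and its adjusted p was 0.0554 without IVF library 3. The mean log2 difference of the list was -0.006, so rises in some members offset falls in others. Among those that fell, CDK1, a mitotic kinase, had a mean of 171 ± 18.1 in parthenogenetic and 205 ± 16.1 in IVF ESCs. The immediate early and heat shock list passed downward with 0 of 14 called (median -0.19, adjusted p = 0.00247; adjusted p = 0.128 with an estimated correlation), and FOS had 105 ± 16.5 and 148 ± 12.1. The other 22 lists did not pass, with adjusted p from 0.0522 to 0.97; the medians of the epithelial, oxidative phosphorylation, maternally expressed and senescence lists turned negative after quantile normalization.

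**Figure D4:**
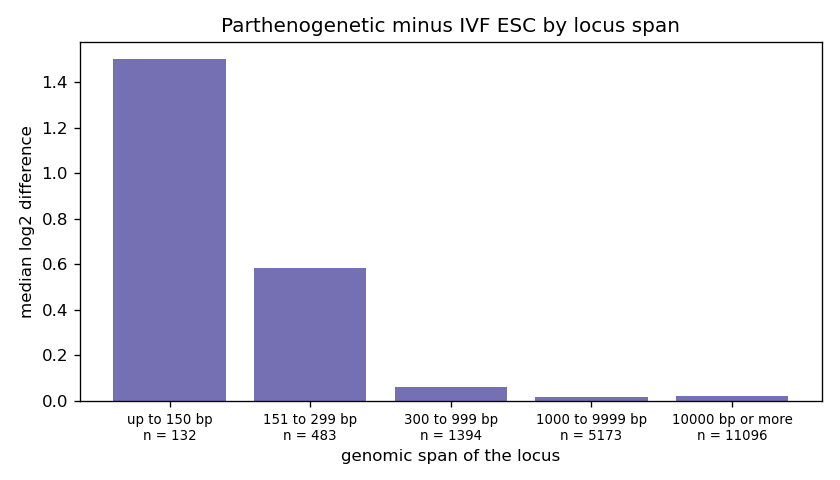
Median log2 difference, parthenogenetic minus IVF ESCs, by the genomic span of the locus, with the number of loci in each class. The median is 1.50 at spans up to 150 bp, 0.58 at longer spans under 300 bp and 0.02 from 1 kb upward.

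In all, 402 loci were called, 278 higher and 124 lower in parthenogenetic ESCs, at 18278 tested. On Ensembl loci 128 were called, 66 higher and 62 lower, and loci under 300 bp supplied 45 and 70 of the higher ones at spans up to 150 bp and at longer spans. ESC3 differed from ESC11 at 454 loci (272 higher, 182 lower) and ESC7 at 537 (391 higher, 146 lower). After quantile normalization the splits were 175 higher and 201 lower for ESC3, and 292 and 179 for ESC7. With Ensembl loci alone they were 71 and 92 for ESC3, and 125 and 80 for ESC7. Scaling to the same sum gave 57 and 6832 for ESC3, and 99 and 2666 for ESC7. The excess of higher loci in ESC3 thus depends on the setting. Both lines shared 115 higher and 67 lower loci, where independent calls would give 5.82 and 1.45, and 19 loci were called in opposite directions. The shared IVF libraries may add to the overlap. Simulated unchanged data gave 0, but they hold no changed gene and cannot show how much those libraries add. Scaling to the same sum moved the median of all loci to -0.89 and turned the split to 73 higher and 4633 lower, and moved the list medians with it. With that scaling CYP2C18, TNFRSF10B, SLC1A3, TWIST2 and HOXC8 were at 0.87, 0.77, 0.35, 0.21 and 0.32, and with a pseudocount of 5 FUT4, PEG3, DIRAS3, MAGEL2, TWIST2 and HOXC8 were at -0.60, -0.57, -0.30, -0.71, 0.54 and 0.82, all below the fold minimum. Each line against the mean of the others gave 445 called loci for ESC3, 484 for ESC7 and 402 for ESC11. Of the 25 lists 3 passed camera's test, 1 with an estimated correlation, and 14 passed fry, while 5 passed camera's test without IVF library 1. Counts adjusted over the list alone were the same as over all loci. The core pluripotency, germ cell, WNT, maternally expressed and senescence lists had a median, mean and test that differed in sign.

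The comparison of the 2 parthenogenetic lines asks how far lines of like origin differ. MAGEL2, an imprinted ubiquitin-ligase partner (chromosome 1, 158314803 to 158317091), fell from 21.4 ± 1.77 in ESC3 to 0.596 ± 0.140 in ESC7 (SD, n = 3 each), a log2 difference of -3.81 ± 0.09 (adjusted p = 1.22e-09). MEST, an imprinted hydrolase-like gene (chromosome 18, 19327494 to 19347714), fell from 13.7 ± 0.306 to 2.16 ± 0.0922, beside 12.5 ± 0.649 in IVF ESC11. LEFTY2, the NODAL antagonist, fell from 99.7 ± 11.9 to 16.3 ± 0.853, and TUBB3, a neuronal tubulin, from 245 ± 17.4 to 44.7 ± 3.71. ANXA1, a phospholipid-binding protein, rose from 14.4 ± 1.22 to 270 ± 15.2, and was at 369 ± 8.0 in fibroblasts. AIRE, the autoimmune regulator, had 0.0114 ± 0.0197 in ESC3 and 96.7 ± 45.9 in ESC7 (adjusted p = 0.000394).

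Of 15 paternally expressed imprinted genes, 4 fell from ESC3 to ESC7 and 0 rose (median -0.02, adjusted p = 0.0888; after scaling to the same sum 0.02, but -0.185 relative to all loci). They were MAGEL2, MEST, PEG3, from 2.75 ± 0.336 to 0.406 ± 0.00952, and MKRN3, from 2.56 ± 0.463 to 0.0156 ± 0.0205. MAGEL2 and MKRN3 lie in 1 region of chromosome 1, MKRN3 at 158354954 to 158363850. SNRPN stayed low in both lines, at 0.143 in ESC3 and 0.126 in ESC7. The 2 maternally expressed genes called of 14 were again KCNQ1 and ATP10A on short unannotated loci (adjusted p = 0.58), and the ATP10A adjusted p was 0.103 without ESC3 library 2.

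In other lists few members were called between the lines, while the epithelial and NODAL medians were 0.31 and -0.458. The epithelial list passed upward with 1 of 17 called (adjusted p = 0.00552; adjusted p = 0.102 with an estimated correlation), CLDN10, a claudin, from 9.09 ± 0.937 to 50.6 ± 5.03. The NODAL list passed downward with LEFTY2 the 1 of 10 called (adjusted p = 0.00563; adjusted p = 0.327 with an estimated correlation). Of 13 mesenchymal genes TGFBR2, a TGF-beta receptor, rose by 1.39 and CDH2, neural cadherin, fell by 1.06 (adjusted p = 0.585 for the list); CDH2 was at -0.95 without ESC3 library 2 and -0.75 without ESC7 library 2. SPARC, a matrix protein, rose by 1.06 and was at 0.95 without ESC7 library 3, and COL5A2, on a short unannotated locus, rose by 1.86. They were the 2 of 27 fibroblast and matrix genes called (adjusted p = 0.102 for the list). GATA6, of the mesendoderm list, rose by 1.08 and was at 0.96 without ESC3 library 1 (adjusted p = 0.543 for the list). DUSP5 was the one FGF and MEK target called, higher by 1.08, and IL6 the one senescence gene, higher by 1.26, each list at adjusted p = 0.0888. TUBB3 was the one neural gene called (adjusted p = 0.22 for the list).

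With 0 called members, the cell cycle (adjusted p = 0.00563; adjusted p = 0.409 with an estimated correlation), core pluripotency (adjusted p = 0.0227; adjusted p = 0.327 with an estimated correlation) and primed epiblast lists (adjusted p = 0.0318; adjusted p = 0.436 with an estimated correlation) passed downward. Their medians were -0.12, -0.16 and -0.19, or -0.142, -0.179 and -0.211 relative to all loci. Scaling to the same sum moved the median of all loci to 0.207 and the lists to 0.17, 0.129 and 0.118, so relative to all loci they stayed negative, at -0.037, -0.077 and -0.088. The primed epiblast adjusted p was 0.0561 without ESC7 library 1. OTX2 had 72.2 in ESC3 and 38.5 in ESC7, below the fold minimum.

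Among other Ensembl loci, MX1, an interferon-induced GTPase, fell from 23.3 ± 0.983 in ESC3 to 2.18 ± 0.302 in ESC7, QTRT1, a tRNA-modifying enzyme subunit, from 7.69 ± 0.780 to 0.0832 ± 0.112, and CCDC67 by 2.54 on the log2 scale. EPHB1, an ephrin receptor, fell from 44.3 ± 12.5 to 8.26 ± 7.34, a log2 difference of -2.98 that ran from -3.69 to -1.73 when 1 library was left out and stayed called. ZNF782 was listed at 0 in ESC3 and had 11.8 ± 0.135 in ESC7, and HENMT1, a small-RNA methyltransferase, rose from 1.18 ± 0.257 to 26.0 ± 1.50. OR51Q1, named for an olfactory receptor, had 0.00427 ± 0.00739 in ESC3 and 20.8 ± 1.70 in ESC7.

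In all, 618 loci were called between the parthenogenetic lines, 428 higher and 190 lower in ESC7, of which 315 were Ensembl loci (226 higher, 89 lower). Scaling to the same sum gave 214 higher and 45 lower, with QTRT1, CCDC67, CDH2 and PEG3 at -0.99, -0.83, -0.67 and -0.35. With a pseudocount of 5, MKRN3, PEG3, GATA6, CDH2 and IL6 were at -0.59, -0.52, 0.41, -0.96 and 0.54, below the fold minimum, and EPHB1 had an adjusted p of 0.0532 with a pseudocount of 0.1. Of the 25 lists 5 passed camera's test, 1 up and 4 down, and 0 with an estimated correlation, where fry had 19. Counts adjusted over the list alone were the same as over all loci, and the neural and oxidative phosphorylation lists had a median, mean and test that differed in sign.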

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

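The tests of admixed cells and of a length-dependent library difference were chosen only after the results were seen, and the test on the genes that short loci are named after was planned before its result was seen. No library was tested as far from the others of its group of 3, but fits with library weights and without each library in turn are among the settings. The genes below differed from IVF ESC11 by unequal amounts in the parthenogenetic lines, tested in limma as the difference between the lines.

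For VTI1A, the ESC7 difference from IVF ESCs minus that of ESC3 was -1.46 ± 0.17 on the log2 scale (adjusted p = 8.3e-05), with means of 240 in ESC3 and 86.2 in ESC7. For MUCAP_PIG it was 3.69 ± 0.23 (adjusted p = 1.34e-06), for TNFRSF10B 1.27 ± 0.20 (adjusted p = 0.000655) and for SLC1A3 1.27 ± 0.07 (adjusted p = 4.06e-07), all higher than IVF ESCs in both lines and most so in ESC7. For KCNQ1, on an unannotated locus of 124 bp, it was 13.27 ± 0.34, with 0 in every ESC3 library. For ATP10A, on an unannotated locus of 186 bp, it was 1.46 ± 0.48 (adjusted p = 0.0345), and 4 of the fits without 1 library lost that call.

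Paternally expressed imprinted genes made up a further pattern. PEG3 differed between the lines by -1.41 ± 0.07 (adjusted p = 2e-07) and MEST by -2.22 ± 0.04 (adjusted p = 3.33e-10). MEST in ESC3 differed from the IVF line by 0.12 on the log2 scale, and in ESC7 by -2.09. MAGEL2 and MKRN3 showed the same order, while SNRPN, PEG10, NAP1L5, PLAGL1, NNAT and SGCE were low in both lines.

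IVF-line cells mixed into the ESC3 libraries would raise all paternally expressed genes by 1 share of their IVF level. PEG3 would need 56.2%, but MEST would need 112%, MKRN3 139% and MAGEL2 146%. These 3 exceed the whole IVF level, which argues against that for these genes. The largest share among the 6 other genes was 1.92%. Those genes were chosen as called lower in both lines, which by itself held their share below 56.2%, so they add no separate support. Admixed pig fibroblasts would need at least 55.8% of the fibroblast level, and the largest share among 23 fibroblast and matrix genes was 5.37%, for MMP2, which argues against that too, as does the SSEA1 sort. A loss of imprinting at these genes in ESC3 is a candidate explanation that stays open and untested, since the values carry no alleles. Reads from feeder cells of another species were not tested.

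Loci under 300 bp were higher in parthenogenetic than in IVF libraries, by a median of 1.50 up to 150 bp and 0.58 at longer spans. A change of the genes whose symbols they carry is argued against by the Ensembl loci of over 1 kb with those symbols. The median over these 36 loci was 0.0223, beside 0.0162 for all Ensembl loci, and 0 were called higher. A length-dependent difference between libraries in the FPKM may account for it, since libraries of 1 group also differed at these loci. The largest range of medians within a group was 0.63, in ESC7, followed by 0.587 in IVF ESC11 and 0.499 in fibroblasts, and it was 0.0146 in ESC3. Fragment lengths and library batches are not given, and no other biological explanation was tested.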

How the results depend on the processing

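The settings on Ensembl loci alone and on loci of at least 1 kb were chosen only after the data were seen, and the others were planned. The number of called loci per comparison is given in the order ESCs, ESC3, ESC7 and ESC11 against fibroblasts, parthenogenetic against IVF ESCs, ESC3 and ESC7 against ESC11, ESC7 against ESC3, genes changed in all 3 ESC lines vs fibroblast, and genes differing from IVF ESC in both parthenogenetic lines. A pseudocount of 5, which shrinks differences at low FPKM by construction, gave 4554, 4714, 4494, 4521, 225, 264, 248, 219, 3616 and 118. Without a fold minimum they were 16029, 15517, 15518, 15432, 3592, 4210, 5647, 7302, 13685 and 1287, as fewer conditions apply. A pseudocount of 0.1 gave 673, 747, 904 and 1148 for the 4 comparisons between ESCs and 280 shared by both lines. A filter at an FPKM of 5 left 387 between ESC7 and ESC3, with fewer loci tested. Scaling to the same sum gave 4523, 3740 and 3873 for ESCs, ESC3 and ESC7 against fibroblasts, 4706, 6889, 2765 and 259 between ESCs, 2392 shared by all 3 lines and 2403 by both. The sums are ruled by short loci, and this scaling moved the median of all loci between parthenogenetic and IVF ESCs to -0.89. Ensembl loci alone gave 129, 163, 205 and 320 between ESCs and 60 shared by both lines, and loci of at least 1 kb gave 215, 265 and 345 for the 3 comparisons with the IVF line and 103 shared, with fewer loci tested.

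Lists passing numbered 12, 3 and 5 for ESCs against fibroblasts, parthenogenetic against IVF ESCs, and ESC7 against ESC3. They were 7, 1 and 0 with an estimated correlation, and 25, 14 and 19 with fry, which asks another question. For parthenogenetic against IVF ESCs they were 5 with a pseudocount of 0.1, 6 with quantile normalization, 6 with scaling to the same sum, 5 with a replicate term and 5 with loci of a symbol summed. For ESC7 against ESC3 they were 3 with a pseudocount of 0.1, 2 with quantile normalization and 3 on Ensembl loci. The cause was not tested. A higher correlation is not the reason for every list that weakened with an estimated one, since the epithelial list in ESC7 against ESC3 went to an adjusted p of 0.102 with an estimate of -0.033, below the preset 0.01. For the smooth muscle list in ESCs against fibroblasts, camera's p went from 4.37e-09 to 0.000292 with an estimate of 0.001. A weaker p with an estimated correlation thus does not by itself show that members are correlated.

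Sign changes were seen at symbols whose highest locus is unannotated, since these settings read another locus: IKBKAP in ESCs against fibroblasts turned to 1.81 with both added settings, and ATP10A in parthenogenetic against IVF ESCs to -0.0095 with both (adjusted p = 0.949 and 0.951). In other genes without a call, L1TD1 in ESCs against fibroblasts turned to 0.16 with loci of a symbol summed and L3MBTL1 in parthenogenetic against IVF ESCs to 0.23 on Ensembl loci. With scaling to the same sum, which lowered the median of all loci in that comparison, BLCAP, IMPACT, GRB10 and IGF2R turned to -0.79, -0.93, -0.83 and -1.0. SNRPN in ESC7 against ESC3 was near 0 and turned to 0.001 with that scaling, and it ranged from -0.0793 to 0.0844 without 1 library. Of the named genes, the 192 results covered here otherwise kept their direction, apart from those without a value under a setting. A pseudocount of 5 ended 25 of their calls and scaling to the same sum 17.

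Leaving out 1 library gave 7864 to 7899 called for ESCs, 8026 to 8101 for ESC3, 7876 to 7973 for ESC7 and 7795 to 7891 for ESC11 against fibroblasts. It gave 330 to 407 for parthenogenetic against IVF ESCs, 393 to 455 for ESC3 and 476 to 565 for ESC7 against ESC11, 607 to 644 for ESC7 against ESC3, 6355 to 6440 shared by all 3 lines and 153 to 198 by both. Lists passing ranged from 12 to 12, 2 to 5 and 4 to 6, with 5 between parthenogenetic and IVF ESCs without IVF library 1. Replicate numbers do not pair the libraries: 0 of 18 same-number correlations of residuals lay over 0.1. With unlike numbers they ran from -0.1598 (ESC7 library 1 with IVF library 3) to 0.1788 (ESC7 library 1 with IVF library 2). A batch not tied to the replicate number is therefore not excluded. Depth is unknown, so what a low FPKM can resolve cannot be stated.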

Other observations

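The tests of expression level and of a few loci for X-linked loci, of nearness to imprinted genes, and of other splits of the libraries (except for the paternally expressed list) were chosen only after the results were seen. The tests of interferon-stimulated genes and of splits for the paternally expressed list were planned before their results were seen.

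All 13 tested genes of an interferon-stimulated list had a higher mean FPKM in fibroblasts than in any ESC line, which was not tested as a list. B2M, the light chain of MHC class I, had a mean FPKM of 236 in fibroblasts and 24.2, 44.8 and 26.6 in ESC3, ESC7 and ESC11. IFIT3, an interferon-induced antiviral gene, had 20.2 in fibroblasts and 0.183, 0.242 and 0.212 in the lines. Among transposon-derived loci, 46 of 142 loci with the symbol POL were higher and 12 lower in ESCs than in fibroblasts (median log2 difference 0.66), and 19 of 55 named LIN1_NYCCO, for a LINE-1 reverse transcriptase, were higher and 2 lower (median 0.76), beside a median of 0.44 over all loci. These groups were described after their values were seen.

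A difference in interferon response between the parthenogenetic lines was tested because MX1 was lower in ESC7. Over 13 tested genes of a list of 16, which left out the genes already seen, camera in limma gave a median log2 difference of 0.30, opposite in direction to MX1, with an adjusted p = 0.0832 over 26 lists (0.0264 before adjustment). With an estimated correlation the adjusted p = 0.64, and 0 genes were called, so whether these genes differ stays open. Another hypothesis was that unlisted genes nearly absent in both parthenogenetic lines lie near imprinted genes. Of the 4 such genes (KBTBD6, PAMR1, ZNF791 and ABT1), 0 lay within 1 Mb of a listed paternally expressed gene. The test decides nothing, since the median and percentile 95 of 2000 random sets of as many loci were also 0. Listed genes missing from the table, such as NDN, SNURF and ZIM2, and other imprinted genes were not searched.

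Among Ensembl loci with a mean FPKM of at least 5 in some group, X-linked loci were higher in ESCs than autosomal loci were, relative to fibroblasts. The median log2 difference was 0.68 over 347 X-linked and 0.41 over 9540 autosomal loci, and the gap was 0.37 in ESC3, 0.14 in ESC7 and 0.20 in ESC11. The expression level of the loci is argued against, since the X median lay at percentile 100 of 10000 autosomal lists matched on level, whose medians ran from 0.19 to 0.67. Of the X-linked loci 57.9% lay above the autosomal median, at percentile 99.76 of the matched lists (highest 60.8%), and 36.0% were called higher, beside 27.8% of the autosomal loci. A few loci cannot move a median over 347, so these shares restate the shift and are no separate test of whether a few loci carry it. A difference in X dosage between the cells may contribute and stays open. So does the sex of ESC11 and of the fibroblasts, which the labels do not give. ESC3 and ESC7, without a sperm genome, can hold no Y chromosome. No library showed Y expression, as the 11 Y-linked loci had no FPKM above 0.0173 and UTY and SRY were listed at 0, but no library of known male cells shows that these loci can be read.

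Other splits of the libraries were counted for each model result. For ESCs against fibroblasts, 1 of 100 splits, the real one, gave as many as the 7874 called loci, and the highest other had 7828. For the 6425 loci shared by all 3 lines 3 of 100 gave as many (highest other 6805). In both counts chance can be excluded for the grouping of libraries. It is not excluded for cultures or for the choice of fibroblasts, since the libraries of a group may share a culture. The high counts of loci came from the 5 other splits that kept the fibroblasts together, since the highest of the 94 that parted them was 158 called and 60 shared loci. For the 12 lists 4 of 100 gave as many (highest other 13), which excludes chance only weakly: 2 of the splits that parted the fibroblasts also reached 12, so the number of lists hardly tracks the real grouping.

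For parthenogenetic against IVF ESCs, 1 of 100 splits gave as many as the 402 called loci (highest other 369). For that count chance can be excluded for the grouping of libraries. For the 182 shared loci 2 of 100 splits gave as many. The highest other, 255, came from a split that parted the IVF libraries, so the shared count does not single out the real grouping. Chance is not excluded for the choice of line, with 2 lines against 1. The counts follow the lines, not the IVF origin alone: the 15 other splits that kept a line together reached 369 called loci, and the 84 that kept none reached 4. Each line against the others gave 445 called loci for ESC3, 484 for ESC7 and 402 for ESC11, so the IVF line does not stand out in number. For the 3 lists chance cannot be excluded, as 44 of 100 splits gave as many (highest other 6). For the paternally expressed list 1 of 100 gave a p as small as 9.96e-17, and the smallest other was 1.95e-16, so chance is excluded for the libraries only by a small margin, and not for the line. With the IVF libraries parted the smallest was 2.05e-16, so this p hardly sets the real grouping apart, and it was 1.55e-07 with no line kept together.

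Comparisons of 3 libraries with 3 allow 10 splits, too few for a share under 0.05. The real and highest other counts were 8062 and 1 for ESC3, 7941 and 0 for ESC7, and 7847 and 1 for ESC11 against fibroblasts. They were 454 and 3 for ESC3 and 537 and 2 for ESC7 against ESC11, and 618 and 2 for ESC7 against ESC3, while for its lists they were 5 and 8, with 3 of 10 splits as large.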
